A study of Callinectes sapidus with 4 samples.

How the data were processed

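RNA from the Y-organs of 4 blue crabs was sequenced, 2 in intermolt and 2 in pre-molt, per the labels and the series design. Per the labels' protocols, glands were kept in a preserving solution, RNA was extracted with Trizol and Illumina libraries were made from it. Per the submitters' processing notes, Trimmomatic, FastQC, RSEM, Bowtie2 and DESeq2 were used, with no versions given. The contig names have the form that the assembler Trinity writes, per the file headers. How reads were filtered, whether they were stranded and which reads went into the assembly are not given in the sources used here.

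FPKM values, 1 per contig and library, were made by the authors and are used as deposited, rounded to 2 decimals. The mean signal per contig, the mean over libraries of counts scaled by size factors, was made by the authors, per the file headers of their comparison table. The same table holds the log2 fold change with its standard error on the log2 scale, as deposited by the authors. Its score, the fold change divided by the standard error, was also made by the authors, per the file headers. Its p-values and adjusted p-values were made by the authors, per the file headers, and the adjusted values cover 54354 of the 158117 contigs with a p-value. The direction of the authors' fold change was read from the FPKM values, where positive goes with higher pre-molt values. No counts per library were used here, so a count test was not run and the test planned for FPKM was the one applied.

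Each library's depth was estimated from its own FPKM values. Contigs of 300 to 600 bases that were the only member of their component were taken, and the total of mapped fragments and a length offset were searched for which low values become whole numbers of fragments. A value within 0.1 of a whole number was counted as whole. Over 20827 contigs with a mean scaled count above 50 in the authors' deposited table, the estimated fragments had a median ratio of 1.02 and a Spearman correlation of 0.995 to that mean. FPKM holds rounding and multi-mapping estimates, so these fragments are estimates and served for depth, for precision weights and for the thinning test, not for a count test.

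Contigs with an FPKM of at least 1 in at least 2 of the 4 libraries were tested, 83831 in all. The test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(FPKM + 1), with pre-molt against intermolt, no covariate, 2 residual degrees of freedom, two-sided, and Benjamini-Hochberg adjustment at 0.05. Differences are on the log2(FPKM + 1) scale and understate the change of low contigs. Simulated data took the intermolt means of the 83831 contigs and their spreads after limma's shrinkage, with 50 contigs changed at each size. On these the same test recovered 2%, 6%, 26% and 82% of changes of 2, 3, 4 and 5 log2 units, with 6 false calls. The shrunken spreads are more even than those of the contigs themselves, so this recovery can overstate that on the real data. A version with precision weights on the estimated fragments was tried on another simulation. It drew Poisson fragments around the contigs' means with 1 fixed spread of 0.6 log2 between libraries. There the weighted version recovered 0% at each of these sizes when the same FPKM filter was used. With at least 10 fragments in at least 2 libraries (46060 contigs) it recovered 28%, 66%, 96% and 100%, with 3 false calls. Other summaries used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

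Before the data were examined, 16 gene lists by annotated name, the main test, its alternatives and the rule for naming genes were fixed. The files used here pair no names with contigs and no reference was used, so the lists were replaced by protein signatures searched in the 6 reading frames of each contig. The stop-free stretch had to be at least 60 amino acids long for the longest one of a contig and 100 for others. Each of 56 signature classes is a short conserved pattern of a protein family that stands for one of the planned lists or for a control group. The patterns were written with the files in hand and before any class was tested, except that the values of arginine kinase and calmodulin had been seen. Patterns were tightened only on how many contigs they matched in reversed sequences, and the 52 classes whose reversed matches were at most 33.3% of the real ones were kept. A signature shows the family of a contig and not which gene it is, and several contigs can be alternative or partial sequences of one gene.

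Classes with at least 5 tested contigs, 40 in all, were tested with limma's camera at a preset correlation of 0.01, adjusted over the 40. The camera test was repeated with an estimated correlation, and fry, which asks whether a class moves on balance in one direction, gave adjusted p-values of 0.141 for heat shock protein 70, 0.204 for hemocyanin and prophenoloxidase, 0.320 for the symporters, 0.625 for alpha-2-macroglobulin and 0.632 for the LDL-receptor repeats, so that none of these 5 passed it. Within a class, contigs were also adjusted over the list alone. The rule for named contigs fixed beforehand allowed 2 identifiers higher and 2 lower where no names are given, taken by the largest moderated statistic among contigs with a mean FPKM of at least 5 and separated groups. Class examples are the 2 members with the highest mean FPKM and members called in the authors' table, and which of these are printed was chosen after their values were seen. A further 7 signatures were added after abundant contigs with large differences had been seen, and 1 of them had too many reversed matches and was dropped.

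Alternatives were a pseudocount of 0.1 or 5, rescaling by median-of-ratios factors, quantile normalization, no filter or an FPKM minimum of 5, no intensity trend, a threshold of 0.1, a minimum 2-fold change, and each library left out in turn. Keeping 1 contig per component gene and both versions of the precision weights were chosen after seeing the data. With 2 crabs per group, limma p-values for single contigs rest on the spread between these animals, shared over contigs. Camera p-values at the preset correlation set the contigs of a class against the other contigs and treat them as nearly independent. They do not measure the spread between crabs. Bootstrap and binomial intervals cover contigs or counting only. Annotation by sequence similarity was not analysed here.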

Results

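The Y-organs are paired glands in the head region of crabs that make ecdysteroids, the steroid hormones that start molting. RNA was sequenced from the Y-organs of 4 blue crabs (Callinectes sapidus), 2 in intermolt, the long stage between molts, and 2 in pre-molt, when the animal prepares to shed its shell. Reads had been assembled into a transcriptome without a genome, so that each feature is a contig, an assembled transcript sequence. Abundance was given as FPKM, the fragments of a contig scaled by its length and by the mapped fragments of the library. Both pre-molt libraries carried their own substage label: replicate 1 was labelled D2 and replicate 2 was labelled D3. The title of pre-molt replicate 2 carried a different stage code, and the descriptions of both pre-molt libraries ended in the same sample code, so the spread within pre-molt includes stage and rests on these labels. The values of both pre-molt libraries differed throughout, with a Pearson correlation of 0.711 across contigs, and they were treated as separate samples.

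Depth was estimated from the steps between low FPKM values, of which 96.7% to 97.8% per library came out as whole fragments within 0.1 of a fragment. Intermolt replicates 1 and 2 held an estimated 14496000 and 14980000 mapped fragments, and pre-molt replicates 1 and 2 held 20774000 and 13222000. At the median contig length of 331 bases, an FPKM of 1 stood for 2.13, 2.21, 2.97 and 1.95 fragments in the same order. A value of 1 FPKM on a short contig was therefore not distinguishable from counting noise at this depth. Contigs with an FPKM above 0 numbered 81070 and 90801 in the intermolt libraries, 152578 in pre-molt replicate 1 and 93517 in pre-molt replicate 2. In pre-molt replicate 1, 39026 contigs were listed above 0 that were listed at 0 in the other 3 libraries. The 10 most abundant contigs held 20.7%, 14.9%, 20.5% and 19.5% of the summed FPKM of the 4 libraries.

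**Figure D1:**
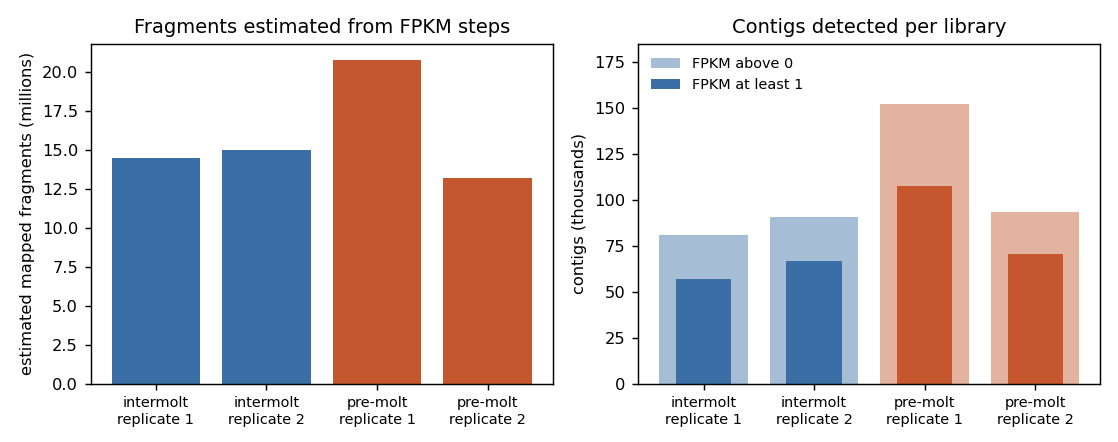
Estimated mapped fragments (left, bars) and contigs detected (right, pale bars for FPKM above 0, dark bars for FPKM of at least 1) in each of the 4 libraries, intermolt in blue and pre-molt in orange. Pre-molt replicate 1 stands apart with 20774000 fragments and 152578 detected contigs, against at most 14980000 and 93517 in the others.

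The assembly held 171530 contigs in 150388 component genes, the assembler's groups of related contigs, with 105129234 bases in all. The median contig was 331 bases long, the N50 was 940 bases, the longest contig had 16027 bases and the GC content was 42.9%. Contigs under 500 bases made up 70.8% of the assembly, and the N50 of the 50035 contigs of at least 500 bases was 1777. Across 83831 contigs with an FPKM of at least 1 in at least 2 libraries, the Pearson correlation of log2(FPKM + 1) was 0.698 between the intermolt libraries and 0.711 between the pre-molt libraries. It lay between 0.548 and 0.625 for the 4 pairs across groups. These are correlations across contigs, which are not independent replicates.

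The series set intermolt against pre-molt glands to find genes whose expression differs as the animal approaches a molt. Contigs whose translation carries the signature of heat shock protein 70, a family of protein-folding chaperones, rose in pre-molt as a class, with a median difference of 1.75 log2 over 12 contigs, 10 of them higher. Contigs with the signature of sodium-coupled neurotransmitter symporters, membrane carriers of transmitters and amino acids, had a median difference of 3.04 over 5 contigs, of which 4 from 1 component gene were higher and the other, from the only other component gene, had a difference below 0. Contigs with the signature of hemocyanin and prophenoloxidase, the copper proteins of crustacean blood that carry oxygen and start melanin formation, fell by a median of 2.57 log2 over 6 contigs, all 6 lower. Contigs of the alpha-2-macroglobulin type, protease-trapping proteins of the blood, fell by a median of 1.70 over 9 contigs in 3 component genes, 7 of them lower. Contigs with repeats of the LDL-receptor class A type, found in lipoprotein receptors, fell by a median of 0.46 over 27 contigs, 20 of them lower, and each of these 5 classes had an adjusted p = 0.953 with an estimated correlation.

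These 5 of 40 signature classes passed limma's camera test at an adjusted p of 0.05 or less, with adjusted p-values of 0.0203 for heat shock protein 70, 0.0203 for the symporters, 1.16e-06 for hemocyanin and prophenoloxidase, 0.0410 for alpha-2-macroglobulin and 0.0465 for the LDL-receptor repeats. With an estimated correlation, 0 classes passed. That version rests on the 2 residual degrees of freedom, so it has little power and cannot show that correlation within classes accounts for the 5. For heat shock protein 70 the estimated correlation was -0.066, below the preset 0.01, yet its unadjusted camera p rose from 0.00152 to 0.0791. The estimated correlation was 0.80 for hemocyanin and prophenoloxidase, 0.90 for the symporters, 0.68 for alpha-2-macroglobulin and 0.15 for the LDL-receptor repeats. With 1 contig kept per component gene 0 passed either, at 0.179 for heat shock protein 70 and 0.248 for the LDL-receptor repeats, while the other 3 of the 5 kept too few contigs to be tested. Without intermolt replicate 2 the adjusted p for heat shock protein 70 was 0.0958, and without intermolt replicate 1 it was 0.153 for the symporters. Alpha-2-macroglobulin had 0.357 without intermolt replicate 1 and 0.182 without pre-molt replicate 2, and the LDL-receptor repeats had 0.357 without intermolt replicate 1 and 0.733 without pre-molt replicate 1, where their median difference shrank to -0.06. The hemocyanin class kept only 2 tested contigs without either intermolt library and was not tested there. The median difference of all tested contigs was 0.21 log2 in favour of pre-molt, and class changes are relative to it. The shift was 0.09 with median-of-ratios scaling and -0.02 after quantile normalization, and the 5 classes kept their direction under both, although alpha-2-macroglobulin and the LDL-receptor repeats did not pass after quantile normalization (adjusted p 0.0841 and 0.0805).

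**Figure D2:**
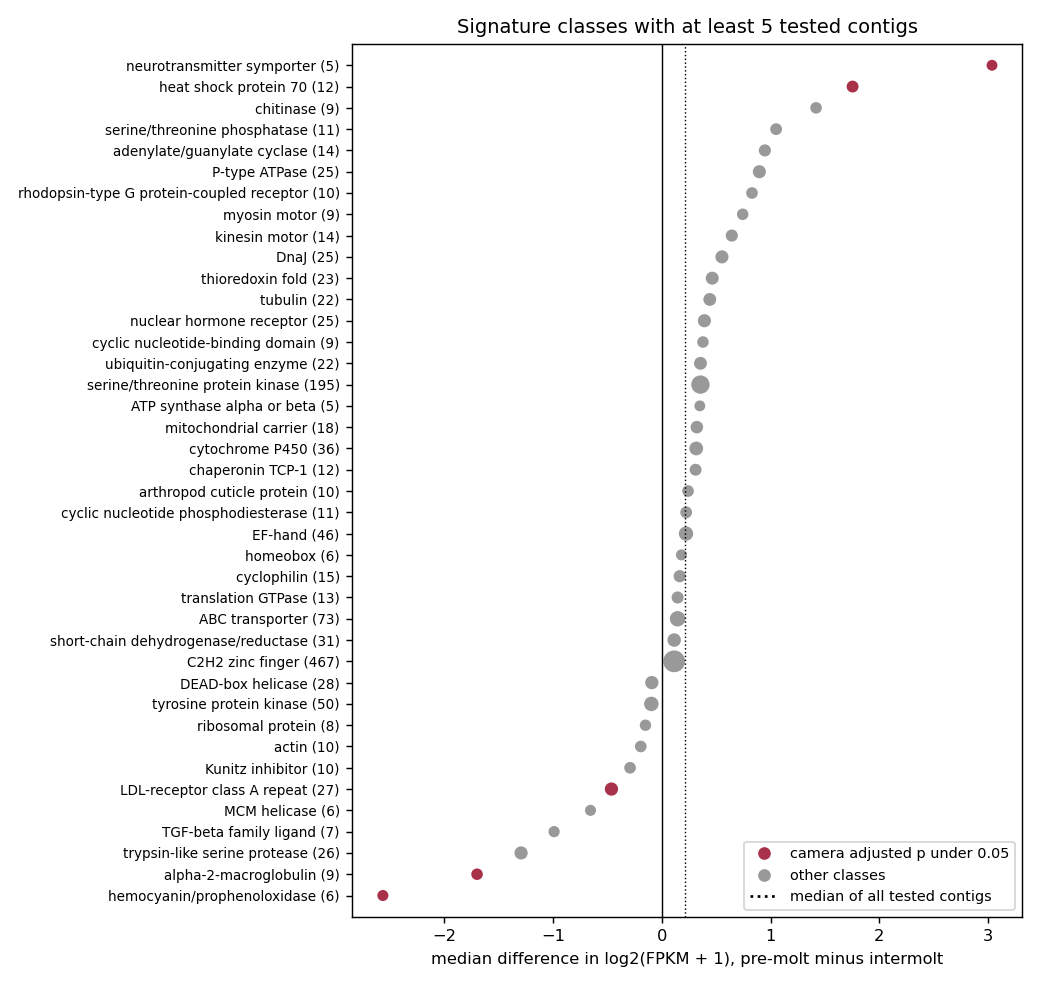
Median difference in log2(FPKM + 1), pre-molt minus intermolt, of the tested contigs in each of the 40 signature classes with at least 5 of them (number in brackets, larger points for more contigs). Red points passed camera at the preset correlation and the dotted line is the median of all tested contigs, 0.21. The symporters stand highest at 3.04 and the hemocyanin and prophenoloxidase class lowest at -2.57. With an estimated correlation, in a version that rests on 2 residual degrees of freedom, each of the 5 red classes had a camera adjusted p = 0.953.

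The second most abundant heat shock protein 70 contig had 52.5 ± 1.58 FPKM (SD, n = 2) in intermolt and 208 ± 21.9 in pre-molt, and the third had 4.53 ± 1.63 and 72.6 ± 51.1. The most abundant of this class overlapped between groups, at 509 ± 98.9 and 756 ± 265. Adjusted over the list alone, 5 of the 12 passed limma, all higher in pre-molt and spread over 4 component genes, while 0 passed over all contigs tested. The most abundant symporter contig had 55.8 ± 15.0 FPKM in intermolt and 367 ± 67.1 in pre-molt (SD, n = 2), and another had 3.10 ± 3.16 and 126 ± 19.6. The 4 symporter contigs that passed adjusted over the list alone belong to 1 component gene, so they are alternative sequences of what the assembler took for a single gene. Of the hemocyanin type, 5 of 6 contigs in 3 component genes passed adjusted over the list alone, and the third most abundant had 8.53 ± 0.276 FPKM in intermolt and 0.330 ± 0.325 in pre-molt. The second most abundant alpha-2-macroglobulin contig ran against its class, with 19.2 ± 1.51 FPKM in intermolt and 48.9 ± 10.3 in pre-molt. No contig of that class or of the LDL-receptor repeats passed adjusted over the list alone. Adjustment over a list alone was made within each class and not across classes.

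Ecdysteroid synthesis begins with a Rieske oxygenase and goes on through a short-chain dehydrogenase/reductase and several cytochromes P450. Of 36 tested cytochrome P450 contigs, 3 Rieske contigs and 31 short-chain dehydrogenase/reductase contigs, 0 passed limma, whether adjusted over the list alone or over all contigs. A pair of P450 contigs was among the most abundant transcripts of the gland. The first had 29102 and 10448 FPKM in the intermolt replicates and 18405 and 14899.9 in the pre-molt replicates. The second had 27837 and 229 in intermolt and 15994 and 14958 in pre-molt, so the intermolt libraries differed more from each other than the groups did. P450 contigs together held 4.93% and 0.987% of the FPKM of the intermolt libraries and 3.04% and 2.65% of that of the pre-molt libraries. The most abundant Rieske contig had 5449 and 1132 FPKM in the intermolt replicates and 690 and 750 in the pre-molt replicates. Both pre-molt values lay below both intermolt values. The means were 3290.4 ± 3052 in intermolt and 719.8 ± 42.2 in pre-molt (SD, n = 2), a difference smaller than the intermolt SD. The most abundant short-chain dehydrogenase/reductase contig had 84.6 ± 48.5 in intermolt and 523 ± 155 in pre-molt, with an adjusted p of 0.168 in limma over the list alone. In the sterol transport group, 0 of 73 ABC transporter contigs passed, and the most abundant had 507 ± 201 FPKM in intermolt and 211 ± 1.90 in pre-molt.

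Among nuclear hormone receptors, the family that holds the ecdysteroid receptor and the early-response genes, 9 of 25 tested contigs in 8 component genes passed adjusted over the list alone, all 9 higher in pre-molt. The most abundant had 5.38 ± 2.57 FPKM in intermolt and 41.1 ± 0.615 in pre-molt (SD, n = 2), a ratio of 7.65. Another had 0.175 ± 0.00707 and 24.1 ± 17.3, and one more was listed at 0 in both intermolt libraries and at 15.0 and 32.9 FPKM in the pre-molt replicates. The second most abundant contig overlapped between groups, at 28.2 ± 15.1 and 13.2 ± 8.90. As a class the receptors had a camera adjusted p of 0.279. Of the rhodopsin-type G protein-coupled receptors, 3 of 10 contigs in 2 component genes passed adjusted over the list alone, all higher in pre-molt, one of them with 0.30 ± 0.368 FPKM in intermolt and 16.2 ± 9.33 in pre-molt.

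Cyclic nucleotides and calcium are second messengers in the control of Y-organ secretion. Of 9 contigs with a cyclic nucleotide-binding domain, 2 passed adjusted over the list alone, both higher in pre-molt. One of them also carries a protein kinase signature, the make-up of a cyclic nucleotide-dependent kinase, and had 0.265 ± 0.0495 FPKM in intermolt and 18.6 ± 10.5 in pre-molt (SD, n = 2). Its adjusted p in limma was 0.0164 over this list, but 0.291 over the list of serine/threonine kinases, to which it also belongs. The most abundant contig with a cyclic nucleotide-binding domain overlapped between groups, at 57.1 ± 15.8 and 73.4 ± 10.3. Of the 11 phosphodiesterase contigs and the 14 cyclase contigs, 0 passed. A phosphodiesterase contig had 0.785 ± 0.361 in intermolt and 9.10 ± 1.21 in pre-molt, with an adjusted p of 0.0675 over the list alone. Calmodulin, the main calcium sensor, has 2 contigs, the first with 168 ± 27.8 FPKM in intermolt and 138 ± 13.8 in pre-molt and the second with 41.4 ± 10.2 and 25.1 ± 1.80. Neither passed, nor did any of 46 EF-hand contigs. P-type ATPases, which include the calcium pumps, had a median difference of 0.90 over 25 contigs and serine/threonine phosphatases one of 1.05 over 11, each with a camera adjusted p of 0.0530. The most abundant ATPase contig had 38.5 ± 28.1 in intermolt and 164 ± 6.96 in pre-molt.

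Protein kinase contigs of the serine/threonine type (195 tested) and of the tyrosine type (50 tested) had 0 passing, with camera adjusted p-values of 0.473 and 0.186. At an unadjusted limma p under 0.05, the serine/threonine type had 28 of its 195 contigs, 24 of them higher and 4 lower in pre-molt. Over all tested contigs 16.1% had such a p, 78.1% of them higher, so the kinases did not stand out in number. The most abundant ligand of the TGF-beta family overlapped between groups, with 71.8 ± 52.6 FPKM in intermolt and 139 ± 111 in pre-molt. The third had 30.9 ± 24.2 and 4.11 ± 0.983, and the 7 contigs of that class had a camera adjusted p of 0.0649. Of 8 contigs with conserved ribosomal protein peptides, 13 translation GTPases, 5 ATP synthase subunits, 18 mitochondrial carriers, 6 MCM helicases, 14 kinesins and 4 core histones, 0 passed in either way. The most abundant ribosomal protein contig had 1659 ± 398 FPKM in intermolt and 1954 ± 197 in pre-molt. Of the other folding proteins, 1 of 15 cyclophilin contigs passed adjusted over the list alone, with 3.08 ± 0.205 FPKM in intermolt and 229.9 ± 69.2 in pre-molt, a ratio of 74.8. One of 25 DnaJ contigs passed too, listed at 0 in both intermolt libraries and at 13.1 and 19.1 FPKM in pre-molt. The heat shock protein 90 contig with the highest mean overlapped between groups, at 140.3 ± 39.7 and 210.3 ± 147.

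Markers of other tissues went in both directions. The symporters and the rhodopsin-type receptors stood for nervous tissue, so 2 of the 3 classes taken as its markers had contigs that passed as higher in pre-molt, adjusted over the list alone, while the transmitter-gated ion channels had 0 of 3 passing. Arginine kinase, the phosphate-storing enzyme abundant in crustacean muscle, is represented by 1 contig and had 1423 ± 522 FPKM in intermolt and 71.0 ± 11.1 in pre-molt (SD, n = 2), 20.05 times less than in intermolt. Its adjusted p in limma was 4.35e-04 over the list alone, which holds no other contig, and 0.178 over all contigs. The most abundant actin contig did not follow it, with 1032 ± 99.2 in intermolt and 1096 ± 228 in pre-molt, and 0 of 10 actin and 0 of 9 myosin contigs passed. The actin contigs had a median difference of -0.19 with 6 of 10 below 0, and the myosin contigs one of 0.74 with all 9 above 0. Of the chitinases, enzymes that digest old cuticle before a molt, 5 of 9 contigs in 4 component genes passed adjusted over the list alone, all higher in pre-molt. These were rare transcripts, such as one listed at 0 in both intermolt libraries and at 2.19 and 5.37 FPKM in pre-molt. The most abundant chitinase contig had 56.6 ± 17.4 in intermolt and 28.9 ± 4.42 in pre-molt and did not pass. Cuticle proteins differed between libraries within groups, the most abundant having 394 and 4.02 FPKM in intermolt and 146 and 0.620 in pre-molt, and 0 of 10 passed.

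Trypsin-like serine proteases, a family that includes digestive enzymes, clotting proteases and many others, split in both directions. Of 26 tested contigs, 10 in 7 component genes were higher in pre-molt and 4 in 4 component genes were lower, adjusted over the list alone. The median difference of the class was -1.30, its mean was 0.18 and its camera adjusted p was 0.400. The median was 0.08 with no filter and -0.26 without intermolt replicate 1. The sign of the median therefore depends on the setting. Without intermolt replicate 2 camera had the class as lower, as in the main fit. Leaving out a pre-molt library is no test of its direction, since the filter then drops contigs under 1 FPKM in both intermolt libraries. Several higher contigs are of that kind, such as a contig listed at 0 in both intermolt libraries and at 6.87 and 21.7 FPKM in pre-molt. One contig had 2.71 ± 0.417 FPKM in intermolt and 272 ± 28.8 in pre-molt (SD, n = 2), and another had 49.4 ± 21.8 and 3.60 ± 1.29. Kunitz inhibitors, which block such proteases, also split. One had 122 ± 53.9 in intermolt and 16.6 ± 6.57 in pre-molt and one had 0.205 ± 0.00707 and 41.4 ± 24.5, and both passed adjusted over the list alone. The remaining tissue and control classes had 0 passing contigs (transglutaminase, papain-like, astacin-like and carboxylesterase signatures, ion channels of the transmitter-gated type, C2H2 zinc fingers, homeobox proteins, DEAD-box helicases, tubulins, thioredoxin folds, TCP-1 chaperonins and stalk proteins). Ubiquitin-conjugating enzymes were an exception, with 1 of 22 contigs passing, listed at 0 in both intermolt libraries and at 27.2 and 28.0 FPKM in pre-molt.

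**Figure D3:**
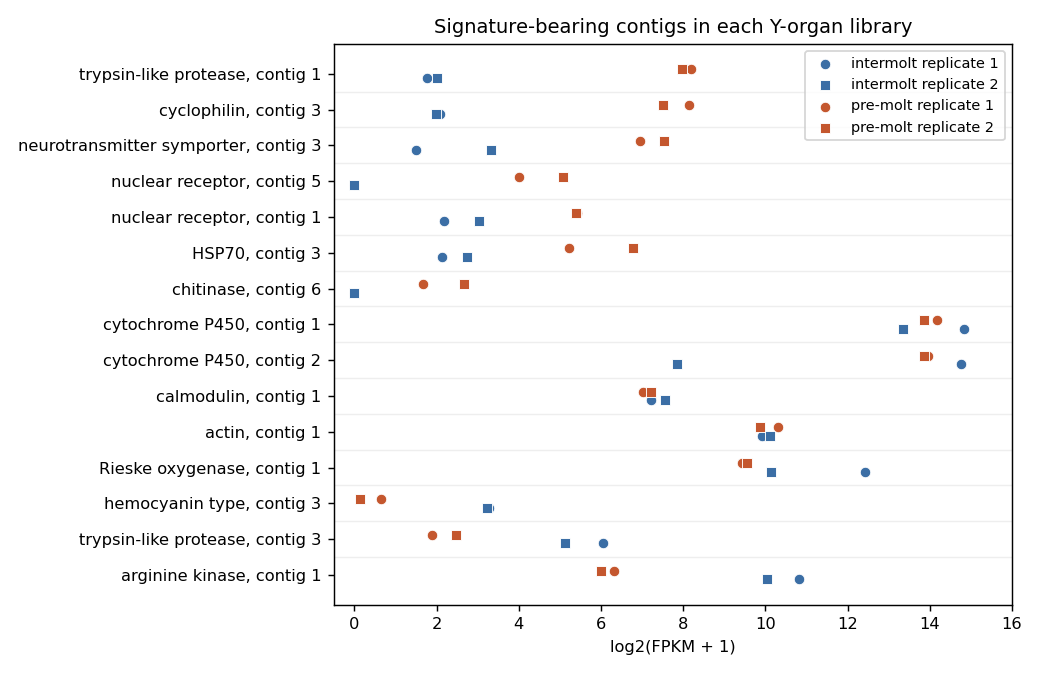
Abundance as log2(FPKM + 1) of 15 contigs in the 4 libraries, each row a contig named by its protein signature and its rank by mean FPKM within the class (intermolt blue, pre-molt orange, circles replicate 1, squares replicate 2). The 7 contigs at the top have both pre-molt points to the right of both intermolt points, cytochrome P450 contig 2 spans 229 to 27837 FPKM within intermolt, and the arginine kinase contig has both pre-molt points, 78.8 and 63.1 FPKM, to the left.

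Over all 83831 tested contigs, limma with an intensity trend on log2(FPKM + 1) called 0 contigs at an adjusted p of 0.05, and the smallest adjusted p was 0.178. At an unadjusted p under 0.05 there were 13531 contigs, 16.1% of those tested, 10571 of them higher and 2960 lower in pre-molt. The split was 6516 higher and 5051 lower after quantile normalization. It was 9179 higher and 3692 lower with median-of-ratios factors. The median difference of the tested contigs was 0.01 log2 without intermolt replicate 1 and 0.42 without intermolt replicate 2, against 0.21 in the main fit. The size of the excess of higher contigs therefore depends on the scaling and on the libraries kept. Leaving out a pre-molt library cannot test the excess. The filter then drops contigs under 1 FPKM in both intermolt libraries, however high they are in pre-molt. With precision weights on the estimated fragments limma called 1608 contigs, a count that was 0 among contigs with at least 10 fragments in at least 2 libraries, where 5403 had an unadjusted p under 0.05, 2420 of them higher and 2983 lower. Without pre-molt replicate 2 the count was 413, and without intermolt replicate 2 it was 16. An exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.333. Both pre-molt values lay on one side of both intermolt values in 44.3% of the tested contigs, and chance alone gives 33.3%.

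The authors' deposited table, which compares the same groups, called 2003 contigs at an adjusted p of 0.05, 1315 of them higher and 688 lower in pre-molt. Of the contigs with an adjusted p in the authors' deposited table, 5 of 26 nuclear receptor, 8 of 26 trypsin-like, 5 of 10 chitinase and 2 of 10 heat shock protein 70 contigs were called higher. Also called higher in the authors' deposited table were 12 of 514 C2H2 zinc finger contigs (1 lower) and 7 of 212 serine/threonine kinase contigs (2 lower). The same held for 3 of 5 symporter contigs, 3 of 84 ABC transporter contigs (1 lower) and 3 of 54 EF-hand contigs (1 lower). Among all 54354 contigs with an adjusted p in the authors' deposited table, 2003 were called. The authors' deposited table called 3 contigs of the hemocyanin type and 2 trypsin-like contigs lower. The cyclophilin contig with the large difference had a log2 fold change of 6.01 and an adjusted p of 3.55e-09 in the authors' deposited table. The cyclic nucleotide-binding kinase contig was called higher in the authors' deposited table, with 5.93 and 2.83e-07 for the same quantities. In the authors' deposited table the arginine kinase contig was called lower, with a log2 fold change of -4.59 and an adjusted p of 3.42e-05. A TGF-beta family ligand was called lower in the authors' deposited table (-3.24, adjusted p 0.0458), and no cytochrome P450, Rieske or short-chain dehydrogenase/reductase contig was called. Both pre-molt FPKM values lay on the called side of both intermolt values for 1945 of the calls in the authors' deposited table, and not for 58. Of the 2003 calls, 1768 were among the contigs tested by limma, and 1706 of these had an unadjusted p under 0.05. Over 49643 contigs with a value in both, the sign was the same in 91.8% and the Spearman correlation of the differences was 0.973.

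The files pair no gene names with contigs, so 2 contigs that were higher and 2 that were lower are given by their identifiers, although none of the 4 passed limma (adjusted p 0.178 each). TRINITY_DN43758_c1_g3_i1, 364 bases long, had 4.99 ± 0.629 FPKM in intermolt and 886 ± 76.2 in pre-molt (SD, n = 2), a difference of 7.21 log2 with an SE of 0.41. TRINITY_DN59803_c0_g1_i1, the trypsin-like contig with the highest mean, is 3800 bases long and differed by 6.20 log2 with an SE of 0.42. TRINITY_DN16018_c0_g1_i1 had 1157 and 1206 FPKM in the intermolt replicates and was listed at 0 in both pre-molt libraries. TRINITY_DN65587_c0_g1_i2 had 155 and 168 FPKM in the intermolt replicates and was also listed at 0 in both pre-molt libraries. In the authors' deposited table all 4 were called, in the same directions, with adjusted p-values of 4.69e-13, 1.26e-12, 1.51e-14 and 1.08e-14.

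Within pre-molt, the library labelled D3 was set against the library labelled D2, with 1 library each and no test. The size of the difference had a median of 0.66 log2 over 83831 contigs, and 2334 contigs were at least 2 log2 units higher and 3789 at least 2 lower in D3. The intermolt replicates, which share a stage label, differed by a median of 0.78, with 5977 and 3209 contigs beyond 2 log2 units. As examples chosen after their values were seen, a cuticle protein contig had 109 FPKM in D2 and 5.66 in D3. A trypsin-like contig had 17.7 in D2 and 102 in D3, and a heat shock protein 70 contig had 36.5 and 109.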

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

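The fits with precision weights, the version with 1 contig per component gene and the split of the authors' calls by FPKM were chosen only after the result was seen. The count of 0 called contigs was also 0 with pseudocounts of 0.1 and 5, median-of-ratios factors, quantile normalization, no filter, no trend, a threshold of 0.1, a minimum 2-fold change, 1 contig per component gene, and weights with at least 10 fragments. It was 1 with an FPKM minimum of 5, where 26767 contigs were tested. The 0 at a threshold of 0.1 holds for the main fit. Under that threshold were 6697 contigs with a pseudocount of 0.1, 562 with an FPKM minimum of 5 and 157 in the weighted fit with at least 10 fragments. Quantile normalization gave 89 and no filter gave 1. A pseudocount of 5, median-of-ratios factors, no trend and 1 contig per component gene gave 0. With precision weights at the main filter the count was 1608, of which 1238 were among the authors' 2003 calls from the same libraries. That fit recovered 0% of the changes simulated with a fixed spread of 0.6 log2, and the cause of the differing count was not tested. With each library left out in turn it ran from 0 to 413, being 16 without intermolt replicate 2 and 413 without pre-molt replicate 2, where the lone sample of a group is assumed to vary like the other group. The count of 5 signature classes was 1 with a pseudocount of 0.1, 9 with a pseudocount of 5, 8 with no filter, 0 with an FPKM minimum of 5, 0 with 1 contig per component gene and 0 with an estimated correlation; an FPKM minimum of 5 leaves the hemocyanin class and the symporters with too few contigs to test, 1 contig per component gene leaves these and alpha-2-macroglobulin so, and otherwise the cause was not tested. With each library left out it ran from 1 (without intermolt replicate 1) to 11 (without pre-molt replicate 1), and the direction of the 5 classes was the same in each setting that tested them. The 4 named contigs kept their direction in each setting that tested them. They had been picked for separated groups and the largest statistics, so this followed from the choice and adds no support. The mean correlation between libraries was 0.685 within groups and 0.462 between groups at an FPKM minimum of 5, against 0.705 and 0.592, and the N50 was 1777 for contigs of at least 500 bases, both on fewer contigs. Of the 2003 authors' calls, 1945 were separated in FPKM. No paired analysis was possible because the replicate numbers follow no shared animal, litter or day and only name the libraries. Count-model alternatives, name-based lists with 1 contig per annotated name, and E-value limits of a sequence match were not run, since no counts per library, names or matches were used here. An FPKM of 1 on a median contig stands for about 1.95 to 2.97 fragments, which limits statements on rare contigs.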

Other observations

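The signatures of the next 2 paragraphs were chosen after the values of abundant contigs were seen, and the tests of the assembly's source reads, of muscle and of blood proteins were chosen only after the result was seen. Phosphoenolpyruvate carboxykinase, the enzyme that commits carbon to new glucose or glycerol, had a contig with 14845 ± 2277 FPKM in intermolt and 441 ± 39.9 in pre-molt (SD, n = 2), and both contigs with its signature passed limma adjusted over the list alone (adjusted p 6.92e-04 each). As the signature was chosen after such values were seen, this is no separate support, and over all contigs tested both contigs had an adjusted limma p of 0.178. In the authors' deposited table the first of them had a log2 fold change of -5.26 and an adjusted p of 1.36e-08. The single S-adenosylmethionine synthase contig, an enzyme that makes the methyl donor of the cell, had 4301 and 343 FPKM in the intermolt replicates and 125 and 169.9 in pre-molt, and it did not pass limma (adjusted p 0.0605 over the list alone). Enolase, a glycolytic enzyme taken for comparison, overlapped between groups with 191 ± 201 in intermolt and 90.2 ± 12.5 in pre-molt.

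Ferritin, the iron-storage protein, had 8227 and 529 FPKM in the intermolt replicates against 131 and 110.3 in pre-molt for its most abundant contig, and 0 of 4 tested contigs passed limma adjusted over the list alone. Of 11 glutathione peroxidase contigs, 2 in 1 component gene were lower adjusted over the list alone, one with 53.9 ± 16.7 FPKM in intermolt and 1.06 ± 0.0707 in pre-molt. Of 8 peroxiredoxin contigs of the 2-Cys type, 2 in 2 component genes were higher adjusted over the list alone, the more abundant with 91.4 ± 46.1 in intermolt and 715 ± 226 in pre-molt. In the authors' deposited table, 3 ferritin, 3 glutathione peroxidase and 2 phosphoenolpyruvate carboxykinase contigs were called lower, and 2 peroxiredoxin contigs were called higher. One more contig of each peroxide-handling class was called in the authors' deposited table against these directions, a glutathione peroxidase contig as higher and a peroxiredoxin contig as lower, and both were listed above 0 FPKM only in pre-molt replicate 1. None of these contigs passed limma over all contigs tested.

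Of the contigs called lower and separated in FPKM in the authors' deposited table, 44 had an intermolt mean of at least 1000 FPKM, and 22 of these had no stop-free stretch of 100 amino acids, with a median of 19.6 times less in pre-molt. Of the separated higher calls in the authors' deposited table, 14 had a pre-molt mean of at least 1000 FPKM, and 10 of these had no such stretch. The 44 contigs, selected for being lower, held 9.81% and 7.84% of the FPKM of the intermolt libraries and 0.359% and 0.614% of that of the pre-molt libraries. Of the separated calls in the authors' deposited table, 576 higher ones (45.3%) were listed at 0 in both intermolt libraries. By comparison, 54 lower ones (8.02%) were listed at 0 in both pre-molt libraries. Detection was uneven, with 152578 contigs above 0 FPKM in pre-molt replicate 1 against at most 93517 in the other libraries. These shares were not corrected for that, so they do not show that more contigs appeared than disappeared in pre-molt. The cause of the imbalance was not tested. Of the calls in the authors' deposited table, 49 had a log2 fold change beyond 20 in size, 42 of them on contigs listed at 0 in 3 of the 4 libraries, and 6 calls had the opposite sign to the FPKM means. One of these was a peroxiredoxin contig listed at 708 FPKM in pre-molt replicate 1 and at 0 elsewhere, which the authors' deposited table gave a log2 fold change of -30.00.

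In pre-molt replicate 1, 39026 contigs (22.8% of the assembly) were detected that no other library held, against 991, 1293 and 1375 contigs found in intermolt replicate 1, intermolt replicate 2 or pre-molt replicate 2 alone. On the assembly as given, deeper sequencing falls short as the whole cause, because thinning that library to the mean depth of the others left 140320 detected contigs against at most 93517 elsewhere. Thinning leaves the assembly unchanged, so it cannot tell whether depth acted through which contigs were assembled. Reads of another organism cannot be told apart from the crab's own. At 300 to 600 bases 21.4% of the contigs found in pre-molt replicate 1 alone (Wilson interval 20.7% to 22.2%) had a stop-free stretch of 100 amino acids. The share was 31.6% for contigs found in all 4 libraries, or 28.0% once matched on length. Against both, the bound written beforehand to exclude another organism was met. Above 500 bases, where the stretch takes a smaller part of the contig, the bound was not met, with 37.0% (Wilson interval up to 40.2%) and 39.5%. The median GC of the contigs of this library alone was 38.7% against 41.5%. It was not matched on length (median 263 against 599 bases), so it points to no source. The assembly may have been built mostly from reads of this library, as contigs need several fragments to assemble and only 10.5% of its low values stood at 1 fragment, against 38.9% to 40.2% in the others. A true difference of this animal or its stage, untested with 1 library, stays open.

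Arginine kinase, a muscle marker, and the hemocyanin-type contigs, taken as markers of blood cells and hepatopancreas, were lower in pre-molt. Muscle left on the intermolt glands cannot be told apart from a change within the gland: the 16 abundant actin and myosin contigs had a median difference of 0.22 log2 (bootstrap interval -0.80 to 1.17), against -4.26 for arginine kinase, but these families also have members outside muscle, and summed actin was 150 FPKM higher in intermolt with an interval of -2972 to 3271, which holds the 1352 FPKM of arginine kinase. Blood cells in the intermolt glands cannot be told apart from a change within the gland either, and carry-over of hepatopancreas was not tested. Of the 12 transglutaminase and Kunitz inhibitor contigs, outside the classes that make the pattern, 10 were Kunitz inhibitors, a control class and not a blood marker. The median of the 12 was -0.29 (bootstrap interval -1.19 to 0.02), which straddles the -1 set as the bound and says little about blood. The most abundant transglutaminase contig, an enzyme of blood clotting, had 100.3 ± 79.7 FPKM in intermolt and 41.8 ± 15.9 in pre-molt, and the hemocyanin-type contigs were themselves rare, all 7 together at 40.7 and 50.9 FPKM in the intermolt replicates. A difference of molt stage stays open for both and was not tested separately.

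The second most abundant cytochrome P450 contig had 229 FPKM in intermolt replicate 2 and 27837 in intermolt replicate 1. Reads divided between near-identical contigs may account for part of this, since it shares 96.9% of its 31-base words with the most abundant P450 contig. As the whole cause this is argued against, because all 17 contigs that share words with the pair summed to 10910 FPKM in that library against 57694, 34793 and 30297 in the others. A general loss of abundant transcripts is argued against as well, with a median ratio of 1.14 (bootstrap interval 0.986 to 1.32) between the intermolt libraries over 147 abundant contigs. Gaps between the intermolt libraries were not confined to steroid enzymes. The most abundant ferritin contig had 8227 and 529 FPKM in intermolt replicates 1 and 2, while the most abundant glutathione peroxidase contig went the other way, with 214 and 1801. A difference between these 2 intermolt animals, in steroid-enzyme transcript or more widely, stays open as a hypothesis, and no biological explanation was tested.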
